A study of Homo sapiens with 54 samples.

How the data were processed

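Poly(A) RNA was purified and made into paired-end libraries with a universal kit for the MGI platform and sequenced on an MGISEQ-2000RS, per the labels' protocols. The processing notes of the submitters name FastQC for read quality, HISAT2 for alignment, StringTie, DESeq2 and the GRCh38 build, with no versions or settings, so which tool counted reads is not given in the sources used here. The authors deposited FPKM values, fragment counts scaled to transcript length and library size, in a single table with 50037 gene entries and 54 library columns, each matched to its sample by title. It also holds 48 columns of 16 comparisons whose groups are not named, and these were not used. The series text speaks of 60 samples with a Torin1 recovery group, which was not analysed here. That text calls the 3 libraries of a group biological replicates, and nothing says that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

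The steps between low FPKM values were used to recover whole reads, within a tolerance of 0.01 read, for 36448 of the 36451 genes above 0 in a library (99.99%). The library sizes behind the deposited FPKM followed median-of-ratios factors of the recovered reads (ratio 0.998 to 1.002), so the values were already scaled between libraries. Precision is limited by counting error for genes near the filter, and such limits cover counting error only. FTH1, EIF4A1 and CRP were listed at 0 in every library, so a 0 in this table can be a failed estimate and is reported only as listed at 0. Many loci have a second entry for an alternate copy, and genes with such copy rows are not named in the text even where they filled a place in the naming rule. Some genes the rule selected are withheld and not reported here. Of the gene symbols, 43732 matched the RefSeq annotation of GRCh38.p14, from which coordinates were taken, counted from 1.

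Each line was fitted with limma (empirical Bayes with a trend) on log2(FPKM + 1), over genes with at least 1 FPKM in at least 3 of its 27 libraries (11395 genes in HCT116 and 11280 in HepG2), with 1 mean per group and no covariate. Each treated group was set against NC and 6 h against 3 h. A fit of all 54 libraries gave the difference of effects between the lines (9683 genes passing in both) and the NC comparison of the lines (12992 genes passing in either). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate low genes. SOCS3 in HepG2 after 3 h of IL-6 stood at log2 2.07, against 4.32 with a pseudocount of 0.1 and 5.48 with voom on the recovered reads. Camera with a preset inter-gene correlation of 0.01 tested those of 32 gene lists that had at least 5 tested members, adjusted over the 392 list tests against NC and separately over 313 others, and was repeated with an estimated correlation. The lists cover signalling targets (JAK-STAT3, NF-kB, interferon, FOXO, ATF4, p53, glycolysis and HIF1), chemokines, immediate early genes, acute phase and negative acute phase proteins, and sterol and fatty acid synthesis. They also cover bile acid metabolism, lysosome and autophagy, ribosomal proteins, ribosome biogenesis, ER chaperones, heat shock proteins, cell cycle phases, histones, mitochondrial genes, matrix genes, receptors, TIMP, MMP and EGF ligand genes, and markers of hepatocytes, colon epithelium, blood cells and fibroblasts. The design, the lists and the naming rule were set before the data were examined.

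The naming rule took, for each comparison with NC, the 6 largest called rises and 6 largest called falls among genes with a mean of at least 5 FPKM in 1 of the groups and all 3 treated libraries on one side of the 3 controls. It added the 4 called members of each list with the largest absolute change, and every tested TIMP, MMP, EGF ligand and receptor gene, called or not. Comparisons of times and lines took 4, 4 and 3. Genes named outside it are said to be chosen after their values were seen.

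The test was run on simulated data with 200 genes changed, 50 at each of 1.25, 1.5, 2 and 4-fold. It recovered 56%, 90%, 100% and 98% of them for IL-6 at 3 h in HCT116 (11157 genes in the step), 62%, 88%, 90% and 98% for the same treatment in HepG2 (11135 genes), 58%, 94%, 98% and 98% for TNF-α at 6 h against 3 h in HCT116 (11153 genes), 62%, 94%, 92% and 96% for the IL-6 difference between lines (9522 genes) and 74%, 84%, 96% and 94% for NC (11856 genes). In that order, 3.4%, 4.5%, 7%, 6% and 5.4% of the calls were unchanged genes. Of 40 unchanged simulated lists, 1 had an unadjusted p under 0.05 (IL-6, 3 h, HepG2), which leaves inter-gene correlation untested. Alternatives covered the pseudocount, the filter, the scaling, the replicate number as a block, the libraries in the fit, the control group and each left-out library; voom, total-read scaling and a fit without copy-row genes were added after seeing the data. Versions were R 4.3.3, limma 3.58.1, version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.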

Results

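Messenger RNA of 2 human tumour lines was sequenced after short exposure to 3 cytokines and a kinase inhibitor: HCT116, a colon cancer line, and HepG2, a liver cancer line that the labels call a liver cancer stem cell. Cells received IL-6 or IL-10 at 50 ng/mL, TNF-α at 100 ng/mL or Torin1 at 1 µM for 3 h or 6 h, or an equal volume of medium (NC), whose labels give no time. Each line had 9 groups of 3 libraries, 54 libraries in all. The series text names the tissue inhibitors of metalloproteinases TIMP1 and TIMP2, the MMP genes and EGF as its focus. The recovered depth was 38.5 to 55.7 M reads on genes in HCT116 and 46.3 to 93.7 M in HepG2. In the shallowest library 1 read on a transcript of 1 kb was worth 0.0244 FPKM in HCT116 and 0.0236 in HepG2. With copy-row genes kept, replicates differed beyond sampling noise (chi-square per degree of freedom at least 6.76 in HCT116, 7.73 in HepG2). Mitochondrially encoded genes took 7.6% to 9.97% of the reads in HCT116 and 10.09% to 12.15% in HepG2. Values are mean ± SD of 3 libraries, log2 values compare the treated group with NC on the log2(FPKM + 1) scale, and gene lists were fixed before the data were examined. Where a called list is given with a camera adjusted p alone, the call also held with an estimated correlation.

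The mock-treated libraries set the starting levels of the genes the study is about. TIMP1, a secreted inhibitor of matrix metalloproteinases, was 78.5 ± 1.88 FPKM in HCT116 and 13.8 ± 0.797 in HepG2 (limma adjusted p = 2.23e-30). In the same order of the lines, TIMP2 was 9.0 ± 0.25 and 4.94 ± 0.208 FPKM, and TIMP3, the inhibitor bound to matrix, was 1.09 ± 0.0987 and 40.1 ± 0.772 FPKM. The EGF receptor ligand genes AREG (190.5 ± 9.43 and 1.76 ± 0.279 FPKM) and EREG (185 ± 9.2 and 0.191 ± 0.10 FPKM) stood far higher in HCT116, and TGFA (log2 1.12) and HBEGF (log2 0.75) were also higher there. BTC was listed at 0 in HepG2 and MMP3 at 0 in HCT116. MMP15 was 5.9 ± 0.279 and 17.3 ± 0.107 FPKM, and MMP14 1.45 ± 0.133 and 2.75 ± 0.249 FPKM. EGF itself stayed under the filter, with no library above 0.0467 FPKM in HCT116 or 0.013 in HepG2. Of 23 MMP genes in the table, 4 passed the filter in HCT116 and 3 in HepG2, and the highest library of the others reached 0.638 and 0.918 FPKM, both for MMP17. TIMP4 reached at most 0.213 FPKM in HCT116 and 0.107 in HepG2. On GRCh38.p14, the annotation places TIMP1 (Entrez 7076) on chromosome X from 47582436 to 47586789, TIMP2 (Entrez 7077) on chromosome 17 from 78852977 to 78925387 and TIMP3 (Entrez 7078) on chromosome 22 from 32801705 to 32863041. It places AREG (Entrez 374) on chromosome 4 from 74445136 to 74455005, MMP14 (Entrez 4323) on chromosome 14 from 22836585 to 22847758 and MMP15 (Entrez 4324) on chromosome 16 from 58025754 to 58046901.

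Across all genes, 11115 of 12992 differed between the lines, 5486 higher in HCT116 and 5629 lower. Scaling to total reads shifted the median of all genes by 0.18 log2. The higher and lower counts were 8844 and 7767 with no filter, 5601 and 5525 with median-of-ratios factors, 6580 and 4606 with total reads. The lactate dehydrogenase gene LDHB (713 ± 20.4 and 0.337 ± 0.419 FPKM), GSTP1 (374 ± 5.21 and 0.101 ± 0.152 FPKM) and CAV1 (238 ± 6.4 and 0.178 ± 0.207 FPKM) were among the highest in HCT116 relative to HepG2, and albumin (ALB, 2.82 ± 0.954 and 7959.9 ± 197 FPKM) and alpha-fetoprotein (AFP, 1.0 ± 0.334 and 3418 ± 112 FPKM) among the lowest. All 17 measured hepatocyte markers were lower in HCT116 (17 adjusted over the list alone, camera adjusted p = 1.67e-10, adjusted p = 0.0923 with an estimated correlation). Of the acute phase proteins 20 of 21 were lower and 1 did not pass (20 lower adjusted over the list alone, camera adjusted p = 9.42e-11). FGG stood at log2 -9.16. Of the negative acute phase proteins, which fall in inflammation, 9 of 10 were lower and 1 did not pass (10 lower adjusted over the list alone, camera adjusted p = 6.15e-06, adjusted p = 0.0739 with an estimated correlation). AHSG stood at log2 -9.64. Of the colon epithelium markers 2 of 6 were higher and 4 lower (2 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.301), and the members higher in HepG2 included FABP1 and the stem cell marker LGR5 (0.0055 ± 0.00211 and 41.1 ± 0.594 FPKM). Among markers of other cell types, the blood cell marker LYZ was high in HepG2 (0.452 ± 0.106 and 1311 ± 8.26 FPKM) and the fibroblast marker COL1A1 low in both (0.874 ± 0.0278 and 0.00462 ± 0.00418 FPKM). IL6ST was 5.98 ± 0.479 and 38 ± 0.975 FPKM and IL6R 1.4 ± 0.116 and 4.27 ± 0.0567 FPKM. IL10RA reached at most 0.248 FPKM in HCT116 and 0.0136 in HepG2, and IL10RB 0.152 and 0.0682 FPKM.

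**Figure D1:**
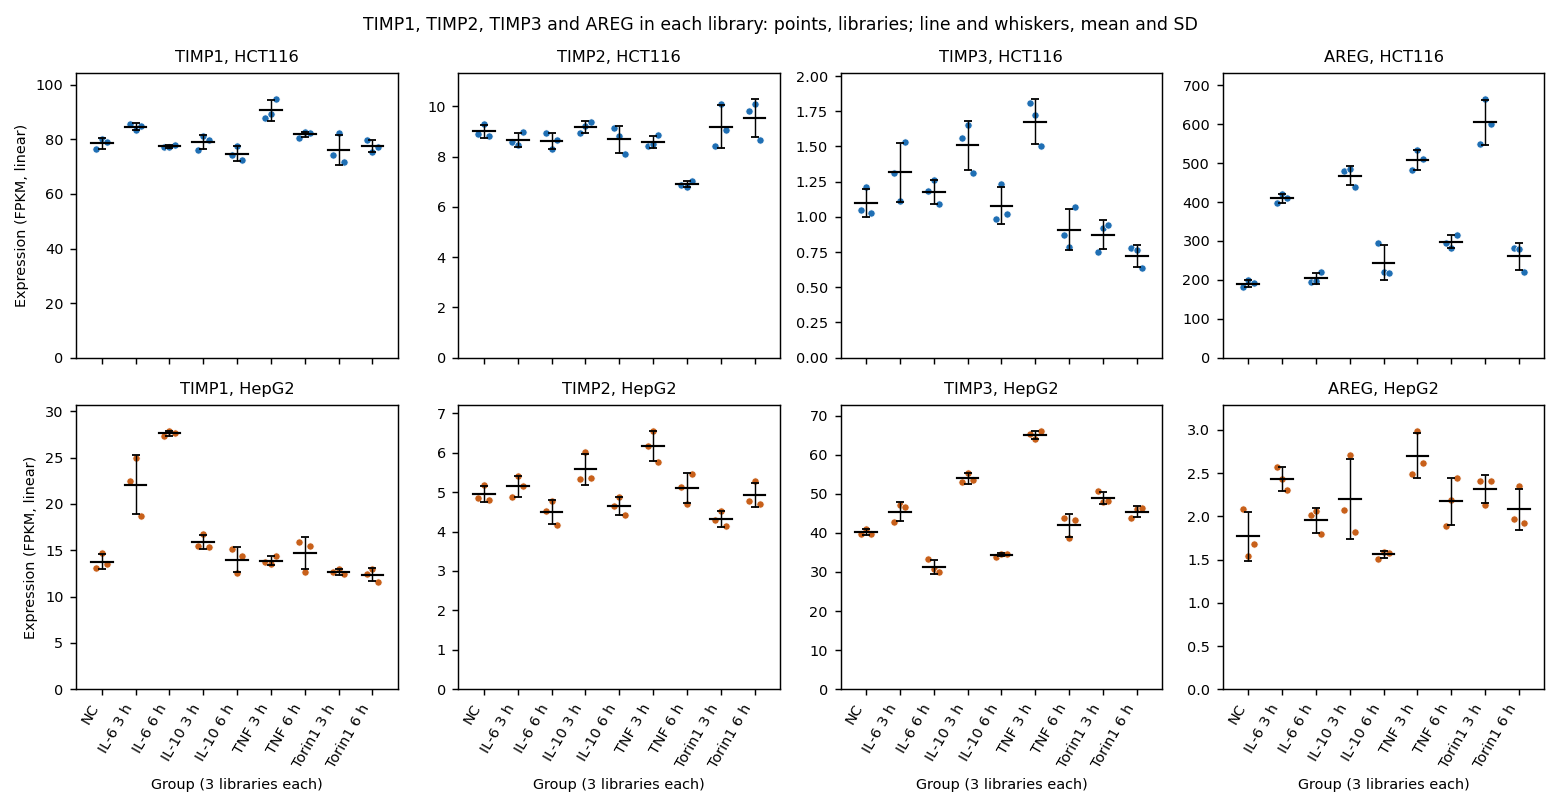
Expression of TIMP1, TIMP2, TIMP3 and AREG (linear FPKM, vertical axis) in the 9 groups of each line (horizontal axis), with 1 point per library and lines and whiskers for mean and SD. TIMP1 in HepG2 stood at 27.6 FPKM after 6 h of IL-6 against 13.8 in NC, and AREG in HCT116 was higher at 3 h than at 6 h under each treatment.

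IL-6 signals through the receptor subunit IL6ST to the transcription factor STAT3, and the first comparison asked what it changed in HCT116. At 3 h, STAT3 itself rose from 11.6 ± 0.447 to 18.1 ± 1.21 FPKM (log2 0.60, limma adjusted p = 2.38e-09). The kinase gene PIM1, a STAT3 target, rose from 4.28 ± 0.454 to 7.23 ± 0.512 FPKM (log2 0.64). The epithelial transcription factor OVOL1 rose from 3.61 ± 0.415 to 14.3 ± 0.967 FPKM (log2 1.73, limma adjusted p = 5.66e-10), and CPA4, a secreted carboxypeptidase gene, fell from 23 ± 2.93 to 11.9 ± 0.22 FPKM (log2 -0.89). Against the IL-10 libraries of the same hour, STAT3 was still higher (log2 0.49, limma adjusted p = 1.46e-06). PIM1 (log2 -0.13), OVOL1 (-0.07) and CPA4 (-0.11) then did not pass, all but CPA4 with the sign turned.

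Of the JAK-STAT3 targets, 13 of 22 rose and 9 did not pass (14 rose adjusted over the list alone, camera adjusted p = 4.55e-08). Among immediate early genes, the first transcripts that growth and stress signals induce, 27 of 33 rose, 2 fell and 4 did not pass (28 rose and 2 fell adjusted over the list alone, camera adjusted p = 2.04e-17, adjusted p = 0.0640 with an estimated correlation). CCN1 (log2 1.41) and DUSP5 (log2 1.15) led that list. In the sterol synthesis list 19 of 25 rose and 6 did not pass (20 rose adjusted over the list alone, camera adjusted p = 1.73e-11), with the cholesterol carrier gene STARD4 at log2 0.94. Of the p53 targets, 15 of 26 rose, 1 fell and 10 did not pass (16 rose and 1 fell adjusted over the list alone, camera adjusted p = 9.28e-07), with the secreted factor GDF15 at log2 0.81 and the cyclin kinase inhibitor CDKN1A at log2 0.66. Ribosome biogenesis genes moved down, where 1 of 40 rose, 24 fell and 15 did not pass (1 rose and 26 fell adjusted over the list alone, camera adjusted p = 3.41e-08). Against IL-10, the calls of the immediate early (camera adjusted p = 0.881), sterol synthesis (0.936) and p53 (0.990) lists were lost. Ribosome biogenesis was placed higher (camera adjusted p = 0.0474, adjusted p = 0.575 with an estimated correlation). Of the JAK-STAT3 targets, 5 of 22 rose (camera adjusted p = 1.10e-07). The log2 value was -0.22 for CCN1, -0.09 for DUSP5, -0.15 for STARD4, -0.25 for GDF15 and -0.06 for CDKN1A, none of them passing.

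AREG, an EGF receptor ligand, rose from 190.5 ± 9.43 to 410.1 ± 11.5 FPKM (log2 1.1, limma adjusted p = 8.65e-08) at 3 h and HBEGF stood at log2 0.71, against log2 -0.19 and -0.21, neither passing, with IL-10 in place of NC. The ligand list gave camera adjusted p = 0.0115, adjusted p = 0.393 with an estimated correlation. The TIMP, MMP and EGF genes were chosen by the study, so counts over those lists are not independent evidence. TIMP1 was 84.7 ± 1.3 FPKM against 78.5 ± 1.88 in NC (log2 0.11, limma adjusted p = 0.0430), a call lost with no filter on low values, with total-read scaling (log2 0.07) and with IL-10 in place of NC (log2 0.10). It was also lost without any 1 of 5 libraries, NC replicates 1 and 3 and each IL-6 replicate (limma adjusted p from 0.0530 to 0.145). TIMP2 (log2 -0.05) and TIMP3 (log2 0.14) did not pass. At 6 h, STAT3 was still higher (11.6 ± 0.447 to 15.1 ± 0.119 FPKM, log2 0.35, limma adjusted p = 5.38e-05), while AREG stood at 204 ± 13.2 FPKM against 190.5 ± 9.43 and did not pass. The chaperone genes DNAJA4 (log2 -0.46) and BAG3 (log2 -0.41) fell. Against IL-10 they did not pass (log2 -0.05 and -0.08). At 3 h 3596 of 11395 genes differed from NC, 1817 higher and 1779 lower (1796 and 1880 with median-of-ratios factors, 1281 and 2543 with total reads, 1416 and 1449 without IL-6 replicate 1, 1473 and 1479 without IL-6 replicate 3, 1499 and 1520 without NC replicate 1, 1478 and 1489 without NC replicate 2). Of these, 24 rose and 6 fell at least 2-fold, 4 and 6 with a copy row, a class whose levels often jumped between replicates. At 6 h 1889 differed, 1268 higher and 621 lower (982 and 840 with median-of-ratios factors, 541 and 1374 with total reads), and 1215 in a fit of only the 6 libraries. Against IL-10, 27 genes differed at 3 h and 13 at 6 h, 0 of them by at least 2-fold. At 6 h 1191 were called without IL-6 replicate 1, 1141 without IL-6 replicate 2 and 1123 without NC replicate 3.

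The IL-10 receptor genes IL10RA and IL10RB both lay under the test filter in HCT116, with failed estimates not excluded. At 3 h of IL-10, the matrix glycoprotein gene THBS1 rose from 2.81 ± 0.439 to 13.4 ± 2.02 FPKM (log2 1.91, limma adjusted p = 6.89e-08), and CCN1, a matricellular immediate early gene, from 11.1 ± 1.35 to 36.4 ± 4.45 FPKM (log2 1.63). AREG rose from 190.5 ± 9.43 to 468 ± 24.9 FPKM (log2 1.29), along with HBEGF (log2 0.92), EREG (log2 0.80) and TIMP3 (log2 0.26). TIMP1 (log2 0.01) and TIMP2 (log2 0.02) did not pass. CPA4 fell from 23 ± 2.93 to 12.9 ± 0.892 FPKM (log2 -0.78).

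Of the immediate early genes, 26 of 33 rose, 2 fell and 5 did not pass (28 rose and 2 fell adjusted over the list alone, camera adjusted p = 1.29e-13, adjusted p = 0.106 with an estimated correlation). In the sterol synthesis list 19 of 25 rose, 1 fell and 5 did not pass (20 rose and 1 fell adjusted over the list alone, camera adjusted p = 5.79e-09), and STARD4 reached log2 1.1. For p53 targets 17 of 26 rose, 2 fell and 7 did not pass (18 rose and 2 fell adjusted over the list alone, camera adjusted p = 2.76e-05), GDF15 leading at log2 1.06. Ribosome biogenesis genes went down, where 1 of 40 rose, 27 fell and 12 did not pass (2 rose and 27 fell adjusted over the list alone, camera adjusted p = 5.79e-09).

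At 6 h AREG was 244 ± 44.4 FPKM against 190.5 ± 9.43 (log2 0.34, limma adjusted p = 0.0196), a call lost with no filter on low values and in a fit of only the 6 libraries (limma adjusted p = 0.115). It was also lost without IL-10 replicate 1 (log2 0.20, limma adjusted p = 0.161), and without NC replicate 1 or NC replicate 3 (limma adjusted p = 0.0716 and 0.0507). DNAJA4 (log2 -0.40) fell. Of the mitochondrially encoded genes, counted as a sign of RNA composition, 6 of 13 fell and 7 did not pass (6 fell adjusted over the list alone, camera adjusted p = 2.55e-04, adjusted p = 0.475 with an estimated correlation). At 3 h 4416 of 11395 genes differed from NC, 2486 higher and 1930 lower (1752 and 2735 with total reads). Of these, 29 rose and 6 fell at least 2-fold, 4 and 5 with a copy row. At 6 h 2332 differed, 1593 higher and 739 lower (1248 and 1077 with median-of-ratios factors, 990 and 1343 with total reads). A fit of only the 6 libraries at 6 h called 1051 genes, and without IL-10 replicate 1 1295 were called.

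TNF-α activates NF-kB, and the question was which genes it moved in HCT116. At 3 h BIRC3, an inhibitor of apoptosis and NF-kB target, rose from 0.435 ± 0.142 to 86.4 ± 4.99 FPKM (log2 5.93, limma adjusted p = 1.15e-22). The neutrophil chemokine CXCL8 rose from 0.182 ± 0.0361 to 50.8 ± 2.59 FPKM (log2 5.45), and the NF-kB inhibitor NFKBIA from 9.54 ± 0.317 to 168 ± 8.39 FPKM (log2 4.0). The adhesion receptor ICAM1 rose from 1.94 ± 0.279 to 39.4 ± 1.98 FPKM (log2 3.78) and the urokinase gene PLAU from 5.01 ± 0.543 to 92.9 ± 2.34 FPKM (log2 3.97). ID1, an inhibitor of differentiation factors, fell from 66.2 ± 4.42 to 28 ± 0.147 FPKM (log2 -1.21), and the glucose transporter SLC2A1 from 79.3 ± 4.42 to 34.5 ± 0.591 FPKM (log2 -1.18). Against IL-10 instead of NC, PLAU stood at log2 2.51 and SLC2A1 at log2 -0.54, both passing.

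Of the NF-kB targets 24 of 25 rose and 1 did not pass (25 rose adjusted over the list alone, camera adjusted p = 1.98e-40), 19 of them at least 2-fold, and their median log2 was 1.71. Of the chemokines and cytokines 10 of 10 rose (10 rose adjusted over the list alone, camera adjusted p = 1.42e-15), CXCL1 at log2 3.22 and CCL20 at log2 2.95. In the interferon response list 10 of 10 rose (10 rose adjusted over the list alone, camera adjusted p = 2.73e-09), with the RNA sensors IFIH1 at log2 1.81 and RIGI at log2 1.62. Of the JAK-STAT3 targets 18 of 22 rose, 1 fell and 3 did not pass (18 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.39e-11), IRF1 leading at log2 2.31. For p53 targets 15 of 26 rose, 1 fell and 10 did not pass (15 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.36e-06), and the pro-apoptotic BBC3 reached log2 2.31. Against IL-10, 10 of 26 rose and 6 fell (camera adjusted p = 0.0101, adjusted p = 0.302 with an estimated correlation). Of the matrix genes 14 of 20 rose, 1 fell and 5 did not pass (14 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.32e-07, adjusted p = 0.129 with an estimated correlation). Those that moved most were not collagens but PLAU, its receptor PLAUR (log2 3.38, 2.02 with IL-10 in place of NC) and THBS1 (log2 3.35, 1.43 with IL-10 in place of NC).

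TIMP1 rose from 78.5 ± 1.88 to 90.6 ± 3.71 FPKM (log2 0.20) at 3 h and TIMP3 from 1.09 ± 0.0987 to 1.68 ± 0.157 FPKM (log2 0.35). At 6 h TIMP2 fell from 9.0 ± 0.25 to 6.9 ± 0.124 FPKM (log2 -0.34, limma adjusted p = 3.32e-05), and neither TIMP1 (log2 0.06) nor TIMP3 (log2 -0.14) passed. MMP7 went from 0.692 ± 0.198 to 1.3 ± 0.176 FPKM (log2 0.45) at 3 h and stood at log2 0.66 at 6 h, and MMP15 fell at both times (log2 -0.20 and -0.34). HBEGF rose from 3.65 ± 0.452 to 11.9 ± 0.351 FPKM (log2 1.48), AREG from 190.5 ± 9.43 to 509 ± 25.8 FPKM (log2 1.41) and TGFA from 19 ± 1.29 to 32.4 ± 1.53 FPKM (log2 0.74) at 3 h. Against IL-10, AREG (log2 0.12), TIMP3 (0.10) and MMP15 (-0.07) did not pass at 3 h, and HBEGF stood at log2 0.56. At 6 h MMP15 stood at log2 -0.17 and TIMP1 passed (log2 0.13). BIRC3 was still at 58.6 ± 1.44 FPKM against 0.435 ± 0.142 at 6 h and CXCL8 at 6.28 ± 0.702 FPKM against 0.182 ± 0.0361, while ID2 fell from 156 ± 2.01 to 47.4 ± 0.943 FPKM (log2 -1.69). Of the NF-kB targets, 25 of 25 rose at 6 h (25 rose adjusted over the list alone, camera adjusted p = 4.67e-42). Of the mitochondrially encoded genes, 11 of 13 rose and 2 did not pass at 3 h (13 rose adjusted over the list alone, camera adjusted p = 6.02e-04, adjusted p = 0.514 with an estimated correlation). At 3 h 4742 of 11395 genes differed from NC, 2189 higher and 2553 lower (2433 and 2364 with no filter, 1453 and 3836 with total reads). Of these, 136 rose and 15 fell at least 2-fold (91 and 7 against IL-10), 4 and 6 with a copy row. At 6 h 3858 differed, 1906 higher and 1952 lower, 84 and 7 of them by at least 2-fold (3 and 5 with a copy row). The 6 h higher and lower counts were 1924 and 1841 with no filter, 1411 and 1197 with a filter of 5 FPKM, 2055 and 1887 with median-of-ratios factors, 1344 and 3187 with total reads, 1667 and 1493 in a fit of only the 6 libraries, 1761 and 1751 without NC replicate 2, 1667 and 1605 without NC replicate 3, 1744 and 1689 without TNF-α replicate 1.

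Torin1 inhibits both complexes of the kinase mTOR, a growth regulator that also restrains FOXO factors through AKT. In HCT116 at 3 h CCNG2, a FOXO target that slows the cell cycle, rose from 0.787 ± 0.0874 to 11.3 ± 0.683 FPKM (log2 2.78, limma adjusted p = 1.65e-16). PIM1 rose from 4.28 ± 0.454 to 32.6 ± 3.96 FPKM (log2 2.67) and the antiproliferative gene BTG1 from 3.48 ± 0.245 to 21.2 ± 1.78 FPKM (log2 2.31). At 6 h UBALD2 rose from 6.75 ± 0.858 to 44.1 ± 1.46 FPKM (log2 2.55, limma adjusted p = 5.02e-15). PDCD4, a translation inhibitor degraded downstream of mTOR, rose from 6.3 ± 0.296 to 25 ± 1.02 FPKM (log2 1.83). The chaperone genes HSPA8 (1655 ± 21.2 to 579 ± 25 FPKM, log2 -1.52, limma adjusted p = 8.41e-16) and DNAJA1 (235 ± 7.53 to 94.3 ± 7.65 FPKM, log2 -1.31) fell at 6 h. DNAJB1 fell at 3 h (78.6 ± 1.02 to 35.5 ± 1.28 FPKM, log2 -1.12), as did the hydroxylase gene JMJD6 (13 ± 0.251 to 4.48 ± 0.241 FPKM, log2 -1.35).

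Of the FOXO targets, 17 of 18 rose and 1 did not pass at 3 h (17 rose adjusted over the list alone, camera adjusted p = 1.27e-11). At 6 h 17 of 18 rose and 1 did not pass (17 rose adjusted over the list alone, camera adjusted p = 7.31e-12). Ribosome biogenesis genes moved down, where 31 of 40 fell and 9 did not pass at 6 h (32 fell adjusted over the list alone, camera adjusted p = 3.01e-09). Of the cytosolic ribosomal protein genes 63 of 77 rose and 14 did not pass at 6 h (63 rose adjusted over the list alone, camera adjusted p = 1.46e-09, adjusted p = 0.535 with an estimated correlation). RPL13A stood at log2 0.44. That list was called higher in 11 of the 16 treated groups of both lines, and against IL-10 24 of 77 rose and 4 fell (camera adjusted p = 0.0104, adjusted p = 0.809 with an estimated correlation). Of the heat shock proteins, 1 of 17 rose, 14 fell and 2 did not pass at 6 h (1 rose and 14 fell adjusted over the list alone, camera adjusted p = 1.84e-06, adjusted p = 0.183 with an estimated correlation). Of the lysosome and autophagy genes 21 of 34 rose, 3 fell and 10 did not pass at 3 h (21 rose and 3 fell adjusted over the list alone, camera adjusted p = 3.65e-04, adjusted p = 0.115 with an estimated correlation). GABARAPL1 went from 7.78 ± 1.02 to 24 ± 0.397 FPKM (log2 1.52) and the autophagy kinase ULK1 stood at log2 0.79. In the fatty acid synthesis list 12 of 14 rose and 2 did not pass at 3 h (12 rose adjusted over the list alone, camera adjusted p = 4.22e-05), its regulator SREBF1 at log2 0.71 (0.34 with IL-10 in place of NC). In the sterol list 21 of 25 rose and 4 did not pass at 3 h (21 rose adjusted over the list alone, camera adjusted p = 4.29e-08, adjusted p = 0.0613 with an estimated correlation). Against IL-10 at 3 h the sterol call was lost (camera adjusted p = 0.368), and of the fatty acid list 7 of 14 rose and 1 fell (camera adjusted p = 0.0295, adjusted p = 0.339 with an estimated correlation).

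AREG rose from 190.5 ± 9.43 to 605 ± 57.7 FPKM (log2 1.66) at 3 h and was 260.0 ± 35.3 FPKM against 190.5 ± 9.43 at 6 h (log2 0.44). MMP14, a membrane-bound matrix metalloproteinase, rose from 1.45 ± 0.133 to 2.25 ± 0.157 FPKM (log2 0.41) at 3 h and stood at log2 0.35 at 6 h. Against IL-10 at the same hour, AREG stood at log2 0.37 at 3 h and 0.09 at 6 h, the latter not passing, and MMP14 at log2 0.26 at 3 h. TIMP3 fell from 1.09 ± 0.0987 to 0.725 ± 0.0782 FPKM (log2 -0.28) and HBEGF from 3.65 ± 0.452 to 2.31 ± 0.312 FPKM (log2 -0.49) at 6 h. TIMP1 did not pass (log2 -0.05 at 3 h and -0.02 at 6 h), although at 3 h it did with total-read scaling (log2 -0.10) and without Torin1 replicate 2 (log2 -0.10). TIMP2 did not pass (log2 0.02 and 0.07), and passed at 6 h without Torin1 replicate 3 (log2 0.13). Of the mitochondrially encoded genes, 8 of 13 rose and 5 did not pass at 3 h (8 rose adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.649 with an estimated correlation). At 6 h 6 of 13 rose and 7 did not pass (6 rose adjusted over the list alone, camera adjusted p = 0.0367, adjusted p = 0.710 with an estimated correlation). At 3 h 6120 of 11395 genes differed from NC, 2861 higher and 3259 lower (3551 and 3278 with no filter, 2274 and 3997 with total reads). Of these, 87 rose and 15 fell at least 2-fold (29 and 7 against IL-10), 6 and 9 with a copy row. At 6 h 6521 differed, 2936 higher and 3585 lower (3688 and 3583 with no filter, 3286 and 3276 with median-of-ratios factors), 65 and 19 of them by at least 2-fold (7 and 11 with a copy row).

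In HepG2, IL-6 is the classic inducer of the hepatic acute phase proteins. At 3 h haptoglobin, encoded by HP, rose from 23.3 ± 3.47 to 131 ± 8.69 FPKM (log2 2.45, limma adjusted p = 2.18e-14). The protease inhibitor SERPINA3 rose from 121 ± 3.83 to 466 ± 60.0 FPKM (log2 1.93), LRG1 from 13 ± 0.382 to 57.5 ± 4.93 FPKM (log2 2.06) and the transglutaminase TGM2 from 2.26 ± 0.105 to 12.6 ± 0.698 FPKM (log2 2.06). SOCS3, the feedback inhibitor of STAT3 signalling, went from 0.0836 ± 0.0363 to 3.58 ± 0.875 FPKM (log2 2.07) at 3 h. It reached 8.61 ± 0.394 FPKM against 0.0836 ± 0.0363 at 6 h (log2 3.15). At 6 h HP stood at 192 ± 0.323 FPKM against 23.3 ± 3.47 (limma adjusted p = 4.96e-16), SERPINA3 at 758 ± 14.4 FPKM against 121 ± 3.83 and the phospholipase PLA2G2A at 18.2 ± 2.96 FPKM against 2.61 ± 0.252. CYP1A1, a xenobiotic-metabolising enzyme gene, fell from 47 ± 3.64 to 15.1 ± 0.678 FPKM at 3 h (log2 -1.57, or -0.43 against IL-10).

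Of the acute phase proteins, 16 of 21 rose and 5 did not pass at 3 h (18 rose adjusted over the list alone, camera adjusted p = 1.19e-16). At 6 h 19 of 21 rose and 2 did not pass (19 rose adjusted over the list alone, camera adjusted p = 1.34e-31). The 6 h median log2 was 0.59. The fibrinogen chain genes FGB (241 ± 2.37 to 633 ± 25.7 FPKM, log2 1.39), FGG (log2 1.22) and FGA (log2 1.08) were among those that rose at 6 h. Of the JAK-STAT3 targets, 20 of 24 rose, 1 fell and 3 did not pass at 3 h (20 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.24e-22). At 6 h 19 of 24 rose, 2 fell and 3 did not pass (20 rose and 2 fell adjusted over the list alone, camera adjusted p = 1.01e-23). JUNB (log2 1.83) and CEBPD (log2 1.7) led them at 3 h. Of the NF-kB targets 17 of 23 rose and 6 did not pass at 3 h (18 rose adjusted over the list alone, camera adjusted p = 1.29e-13). BCL3 stood at log2 1.47. Among chemokines and cytokines 8 of 12 rose, 1 fell and 3 did not pass at 3 h (8 rose and 1 fell adjusted over the list alone, camera adjusted p = 3.50e-06, adjusted p = 0.141 with an estimated correlation). CCL20 rose from 568 ± 28.5 to 1422 ± 55.7 FPKM (log2 1.32). Against IL-10 at 3 h, 9 of 23 rose and 1 fell (camera adjusted p = 0.00230, adjusted p = 0.477 with an estimated correlation) of the NF-kB targets, the chemokine call was lost (camera adjusted p = 0.317), CCL20 did not pass (log2 0.13), and BCL3 stood at log2 0.62 and JUNB at log2 0.71. Of the bile acid and drug metabolism genes 7 of 14 fell and 7 did not pass at 6 h (8 fell adjusted over the list alone, camera adjusted p = 0.00120). The bile acid sensor target NR0B2 stood at log2 -0.47 and the sulfotransferase SULT2A1 at log2 -0.42.

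TIMP1, the inhibitor the study names first, rose from 13.8 ± 0.797 to 22.1 ± 3.19 FPKM (log2 0.63, limma adjusted p = 4.87e-06) at 3 h and stood at 27.6 ± 0.299 FPKM against 13.8 ± 0.797 at 6 h (log2 0.95, limma adjusted p = 3.85e-08), with all 3 treated libraries above all 3 NC libraries at each time. MMP3, a stromelysin, rose from 1.86 ± 0.188 to 3.46 ± 0.452 FPKM (log2 0.64) at 6 h. TIMP3 was 45.5 ± 2.37 FPKM against 40.1 ± 0.772 at 3 h (log2 0.17) and fell from 40.1 ± 0.772 to 31.3 ± 1.85 FPKM (log2 -0.35) at 6 h; with IL-10 in place of NC it was lower at both times (log2 -0.24 and -0.13). TIMP2 did not pass (log2 0.05 and -0.12). TGFA fell from 8.2 ± 0.222 to 5.5 ± 0.263 FPKM (log2 -0.50) at 3 h (log2 -0.29 with IL-10 in place of NC), and the receptor subunit IL6ST rose from 38 ± 0.975 to 58 ± 5.01 FPKM (log2 0.59). IL-6 replicate 3 at 3 h lay apart from replicates 1 and 2 on the first principal component of HepG2 (-3.59 against -7.42 and -7.96) and had the highest residual SD of the line (0.112 log2, median 0.08). Without it 1440 higher and 1761 lower were called at 3 h. At 3 h 3827 of 11280 genes differed from NC, 1633 higher and 2194 lower (1905 and 1735 with median-of-ratios factors, 1140 and 1081 in a fit of only the 6 libraries, 1349 and 1226 with IL-10 in place of NC). Of these, 60 rose and 2 fell at least 2-fold (24 and 8 against IL-10), 6 of the rises with a copy row. At 6 h 2188 differed, 856 higher and 1332 lower (1620 and 1047 with IL-10 in place of NC), 27 and 1 of them by at least 2-fold (2 of the rises with a copy row).

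IL10RA and IL10RB also lay under the filter in HepG2, where IL-10 gave the fewest calls of the 4 treatments at both times. At 3 h THBS1 rose from 72.6 ± 5.08 to 182 ± 25.3 FPKM (log2 1.31, limma adjusted p = 6.44e-09). ANKRD1, a stress-induced cofactor gene, rose from 38.2 ± 3.67 to 126 ± 27 FPKM (log2 1.68) and CCN1 from 10.8 ± 0.956 to 28.1 ± 5.48 FPKM (log2 1.29). The short noncoding RNAs BCYRN1 (11.3 ± 1.34 to 55.5 ± 21.2 FPKM, log2 2.13) and RN7SK (1.98 ± 0.418 to 6.89 ± 2.22 FPKM, log2 1.37) rose as well. Whether their rise in these poly(A) libraries reflects IL-10 was not tested. CYP1A1 fell from 47 ± 3.64 to 20.7 ± 0.303 FPKM (log2 -1.14).

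Of the immediate early genes 24 of 25 rose and 1 did not pass at 3 h (24 rose adjusted over the list alone, camera adjusted p = 5.97e-30). Of the NF-kB targets 18 of 23 rose and 5 did not pass at 3 h (19 rose adjusted over the list alone, camera adjusted p = 3.95e-17). NFKBIA went from 79 ± 2.79 to 149.9 ± 22.4 FPKM (log2 0.90). For JAK-STAT3 targets 11 of 24 rose, 4 fell and 9 did not pass at 3 h (12 rose and 5 fell adjusted over the list alone, camera adjusted p = 1.30e-06). JUNB stood at log2 1.12. At 6 h the NF-kB list stood below NC, where 9 of 23 fell and 14 did not pass (11 fell adjusted over the list alone, camera adjusted p = 1.65e-06, adjusted p = 0.183 with an estimated correlation). TNFAIP3 stood at log2 -0.40. THBS1 (log2 -0.64) also fell at 6 h. FABP1, a fatty acid carrier counted among the colon epithelium markers and also abundant in liver, rose from 346 ± 32.2 to 537 ± 44.7 FPKM (log2 0.63). Of the ER chaperones 9 of 19 fell and 10 did not pass at 6 h (12 fell adjusted over the list alone, camera adjusted p = 3.81e-05, adjusted p = 0.0880 with an estimated correlation).

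TIMP3 was 53.9 ± 1.35 FPKM against 40.1 ± 0.772 at 3 h (log2 0.42) and 34.4 ± 0.43 FPKM against 40.1 ± 0.772 at 6 h (log2 -0.22). TIMP1 (log2 0.19 and 0.02) and TIMP2 (log2 0.14 and -0.07) did not pass, but TIMP2 passed at 3 h with median-of-ratios factors (log2 0.16). Of the mitochondrially encoded genes, 3 of 13 rose and 10 did not pass at 3 h (3 rose adjusted over the list alone, camera adjusted p = 0.00306, adjusted p = 0.628 with an estimated correlation). At 3 h 2149 of 11280 genes differed from NC, 809 higher and 1340 lower (1034 and 892 with median-of-ratios factors). Of these, 17 rose and 2 fell at least 2-fold, 1 of the rises with a copy row. At 6 h 1317 differed, 212 higher and 1105 lower (312 higher and 468 lower with total reads, 291 higher and 586 lower with median-of-ratios factors). A fit of only the 6 libraries at 3 h called 1364 genes, and 1407 were called without IL-10 replicate 2. At 6 h 552 were called without NC replicate 2, 798 without NC replicate 1, 760 without IL-10 replicate 3 and 813 without IL-10 replicate 1.

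In HepG2, TNF-α raised the chemokine gene CXCL3 from 0.79 ± 0.0982 to 20.2 ± 1.56 FPKM (log2 3.57, limma adjusted p = 3.00e-16) at 3 h and BIRC3 from 1.82 ± 0.0767 to 21.3 ± 1.18 FPKM (log2 2.98). CXCL8 rose from 13.6 ± 1.88 to 95.3 ± 8.69 FPKM (log2 2.73) and TNFAIP3, a deubiquitinase that limits NF-kB, from 10.3 ± 0.39 to 64.5 ± 8.33 FPKM (log2 2.53). At 6 h BIRC3 stood at 21 ± 2.0 FPKM against 1.82 ± 0.0767 (limma adjusted p = 5.17e-16). FSTL3, a secreted activin antagonist, had gone from 13.2 ± 0.519 to 101 ± 3.51 FPKM (log2 2.85). HAMP, which encodes the iron hormone hepcidin, fell from 29.7 ± 2.86 to 15.3 ± 2.84 FPKM (log2 -0.92) at 3 h and stood at log2 -1.1 at 6 h. The transcription factor genes MIXL1 (21.2 ± 0.80 to 6.18 ± 0.361 FPKM, log2 -1.63) and CEBPA (40.6 ± 1.21 to 21.3 ± 1.66 FPKM, log2 -0.90) fell at 6 h. Against IL-10 rather than NC, CXCL3 stood at log2 2.18, BIRC3 at 2.32, CXCL8 at 1.94 and TNFAIP3 at 1.74 at 3 h.

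Of the NF-kB targets, 22 of 23 rose and 1 did not pass at 3 h (22 rose adjusted over the list alone, camera adjusted p = 2.32e-41), 16 of them at least 2-fold, with a median log2 of 1.42 (0.90 against IL-10), and 22 of 23 rose and 1 did not pass at 6 h (22 rose adjusted over the list alone, camera adjusted p = 2.32e-41). Of the chemokines and cytokines, 10 of 12 rose, 1 fell and 1 did not pass at 3 h (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 7.41e-14). CCL20 went from 568 ± 28.5 to 2644 ± 126 FPKM (log2 2.22), or log2 1.02 against IL-10. In the interferon response list 6 of 15 rose and 9 did not pass at 6 h (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 8.64e-05). The guanylate-binding protein GBP2 led at log2 1.05. Against IL-10 at 6 h, 6 of 15 rose (camera adjusted p = 0.00748, adjusted p = 0.195 with an estimated correlation) of them. Of the bile acid and drug metabolism genes, 1 of 14 rose, 9 fell and 4 did not pass at 6 h (2 rose and 9 fell adjusted over the list alone, camera adjusted p = 0.0146, adjusted p = 0.0870 with an estimated correlation). CYP7A1, the rate-limiting enzyme of bile acid synthesis, was at log2 -0.42 and the hepatocyte factor HNF4A at log2 -0.33 (-0.50 with IL-10 in place of NC).

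TIMP3 rose from 40.1 ± 0.772 to 65.1 ± 1.01 FPKM (log2 0.68, limma adjusted p = 1.71e-10) and TIMP2 from 4.94 ± 0.208 to 6.17 ± 0.39 FPKM (log2 0.27) at 3 h, and neither passed at 6 h (log2 0.06 and 0.04). TIMP1 passed at neither time (log2 0.01 and 0.08). AREG (1.76 ± 0.279 to 2.7 ± 0.26 FPKM, log2 0.42) and HBEGF (1.77 ± 0.179 to 2.78 ± 0.091 FPKM, log2 0.45) rose at 3 h. At the same time TGFA fell (8.2 ± 0.222 to 5.73 ± 0.0399 FPKM, log2 -0.45). Against IL-10, AREG (log2 0.22) and TIMP2 (log2 0.13) did not pass at 3 h, TIMP3 stood at log2 0.27 and TGFA at -0.24. TIMP3 passed at 6 h (log2 0.28). MMP15 fell at 6 h (log2 -0.18). At 3 h 3350 of 11280 genes differed from NC, 1447 higher and 1903 lower (1634 and 1583 with median-of-ratios factors, 1135 and 2796 with total reads, 1133 and 684 with IL-10 in place of NC). Of these, 78 rose and 2 fell at least 2-fold (25 and 6 against IL-10), 2 and 1 with a copy row. At 6 h 3232 differed, 1339 higher and 1893 lower (1659 and 1379 with median-of-ratios factors, 2129 and 1796 with IL-10 in place of NC), 34 and 4 of them by at least 2-fold (2 and 1 with a copy row).

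Torin1 raised IGFBP1, a FOXO target that encodes a liver insulin-like growth factor binding protein, in HepG2 from 124 ± 5.82 to 864 ± 34.2 FPKM (log2 2.79, limma adjusted p = 3.73e-16) at 6 h. DEPP1, another FOXO target, rose from 14.8 ± 0.109 to 108 ± 5.01 FPKM (log2 2.78), PIM1 from 16.4 ± 0.74 to 93.2 ± 2.49 FPKM (log2 2.43) and the matricellular gene CCN2 from 88.7 ± 2.41 to 445 ± 15.8 FPKM (log2 2.31). At 3 h CCNG2 had already gone from 1.46 ± 0.0422 to 9.74 ± 0.083 FPKM (log2 2.12) and UBALD2 from 5.82 ± 0.627 to 27.1 ± 1.52 FPKM (log2 2.04). DDIT4, a stress-induced inhibitor of mTOR, fell from 41.7 ± 1.94 to 4.5 ± 0.292 FPKM (log2 -2.96, limma adjusted p = 7.42e-20) and the hepatokine gene INHBE from 8.01 ± 0.543 to 0.687 ± 0.0836 FPKM (log2 -2.42) at 6 h. The sterol enzyme gene MSMO1 fell from 107 ± 5.26 to 39.4 ± 0.664 FPKM (log2 -1.42) and CDKN1A from 30.2 ± 1.24 to 10.2 ± 0.373 FPKM (log2 -1.48).

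Of the FOXO targets, 20 of 24 rose, 1 fell and 3 did not pass at 3 h (20 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.29e-15). At 6 h 20 of 24 rose, 1 fell and 3 did not pass (20 rose and 1 fell adjusted over the list alone, camera adjusted p = 9.75e-13). The gluconeogenic G6PC1 stood at log2 1.88. Of the ATF4 targets, 21 of 31 fell and 10 did not pass at 3 h (23 fell adjusted over the list alone, camera adjusted p = 8.26e-07). At 6 h 1 of 31 rose, 26 fell and 4 did not pass (1 rose and 26 fell adjusted over the list alone, camera adjusted p = 2.22e-10). The serine synthesis enzyme PSAT1 stood at log2 -0.79. Of the heat shock proteins 15 of 17 fell and 2 did not pass at 6 h (15 fell adjusted over the list alone, camera adjusted p = 6.15e-09). DNAJA1 stood at log2 -1.16. For p53 targets 2 of 27 rose, 19 fell and 6 did not pass at 6 h (2 rose and 19 fell adjusted over the list alone, camera adjusted p = 3.14e-07). BTG2 stood at log2 -1.21. G2/M genes rose at 3 h, where 27 of 29 rose and 2 did not pass (27 rose adjusted over the list alone, camera adjusted p = 2.61e-15). The kinetochore genes CENPE (log2 1.16) and CENPF (log2 1.02) led. Of the G1/S genes 1 of 28 rose, 25 fell and 2 did not pass at 6 h (1 rose and 25 fell adjusted over the list alone, camera adjusted p = 1.04e-09, adjusted p = 0.131 with an estimated correlation). CDC6 stood at log2 -1.09.

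RICTOR, which defines mTOR complex 2, rose from 5.34 ± 0.0407 to 11.5 ± 0.176 FPKM (log2 0.98) at 6 h. HBEGF went from 1.77 ± 0.179 to 3.29 ± 0.398 FPKM (log2 0.63) and TGFA from 8.2 ± 0.222 to 11.1 ± 0.538 FPKM (log2 0.39) at 6 h. TIMP3 was higher at 3 h (40.1 ± 0.772 to 48.9 ± 1.55 FPKM, log2 0.28) and at 6 h (log2 0.17); with IL-10 in place of NC it was lower at 3 h (log2 -0.14) and higher at 6 h (log2 0.39). TIMP2 fell from 4.94 ± 0.208 to 4.32 ± 0.192 FPKM (log2 -0.16, limma adjusted p = 0.0268) at 3 h, and at 6 h it did not pass (4.93 ± 0.318 FPKM against 4.94 ± 0.208). The 3 h call was lost with no filter (limma adjusted p = 0.0680), with median-of-ratios factors (log2 -0.13) and without any 1 of 3 libraries, NC replicate 2 and Torin1 replicates 1 and 3 (limma adjusted p from 0.0646 to 0.112), and held with IL-10 in place of NC (log2 -0.30, limma adjusted p = 1.72e-04). TIMP1 did not pass (log2 -0.11 and -0.15). It passed against IL-10 at 3 h (log2 -0.30) and at 6 h with the 6 libraries alone (limma adjusted p = 0.0471). At 3 h 5130 of 11280 genes differed from NC, 2189 higher and 2941 lower (2600 and 2215 with median-of-ratios factors). Of these, 76 rose and 7 fell at least 2-fold (36 and 14 against IL-10), 2 and 1 with a copy row. At 6 h 6756 differed, 2948 higher and 3808 lower (3435 and 3202 with median-of-ratios factors), 97 and 39 of them by at least 2-fold (2 and 7 with a copy row).

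**Figure D2:**
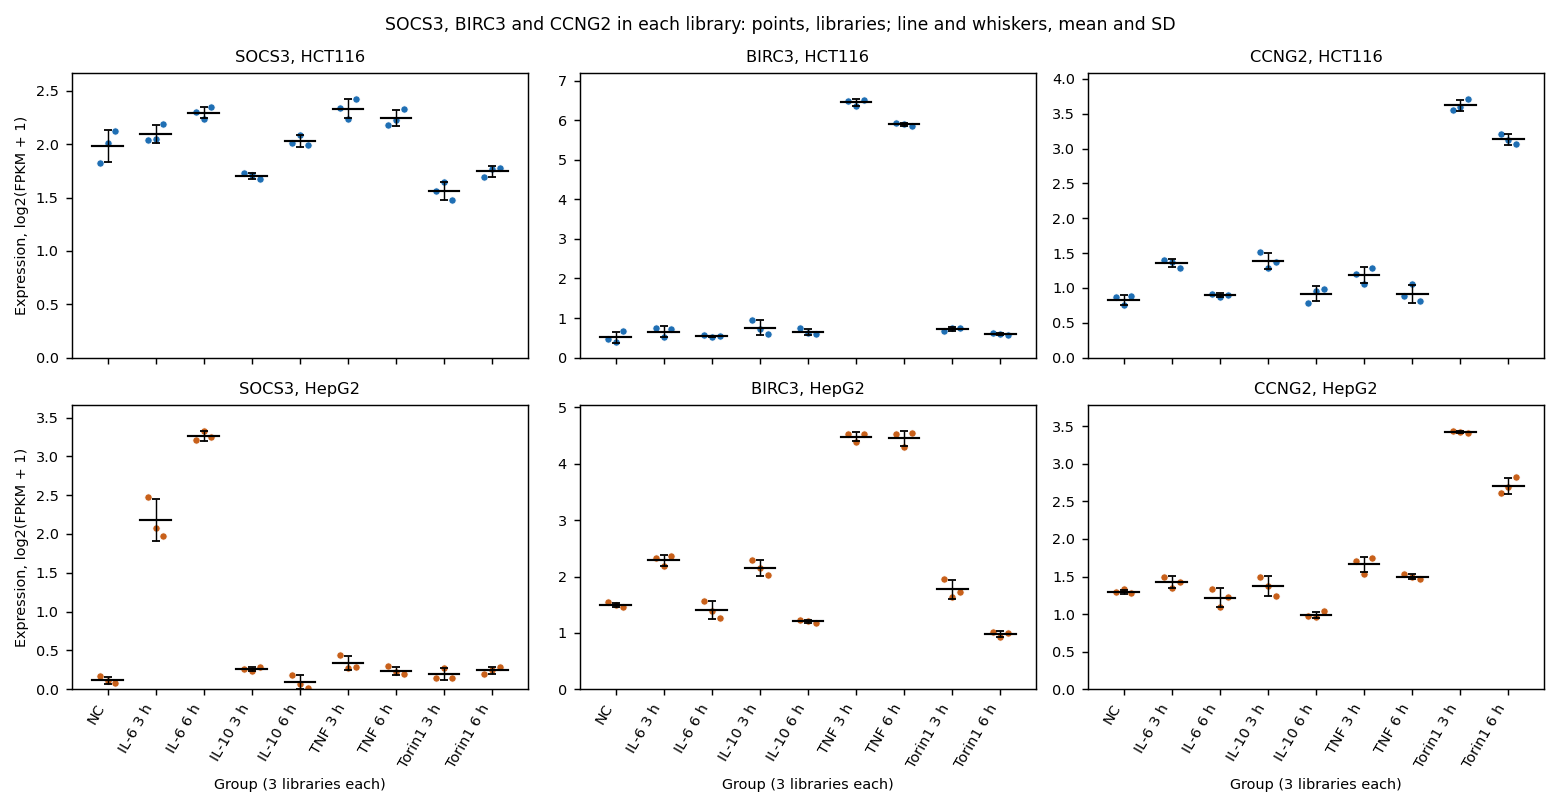
Expression of SOCS3, BIRC3 and CCNG2 as log2(FPKM + 1) (vertical axis) in the 9 groups of each line (horizontal axis), with 1 point per library and lines and whiskers for mean and SD. BIRC3 rose under TNF-α and CCNG2 under Torin1 in both lines, and SOCS3 reached 8.61 FPKM under IL-6 in HepG2.

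**Figure D3:**
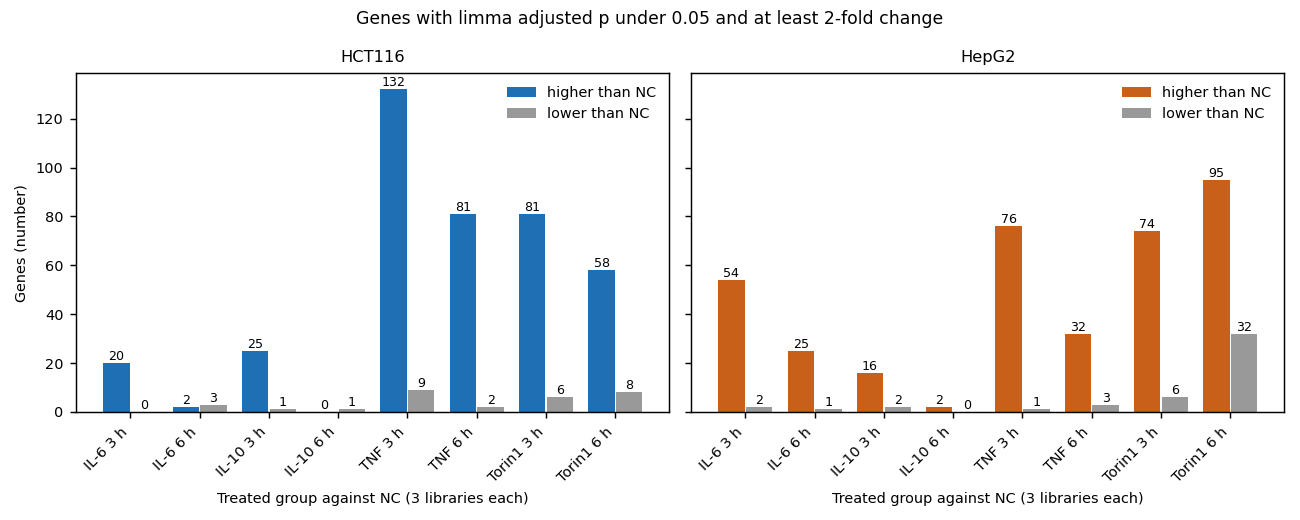
Number of genes (vertical axis) that passed limma and changed at least 2-fold against NC in each treated group (horizontal axis), coloured bars for higher and grey bars for lower, without genes that have a copy row. The tallest bar is the 132 genes higher under TNF-α at 3 h in HCT116, and Torin1 at 6 h in HepG2 has the most lower genes with 32.

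**Figure D4:**
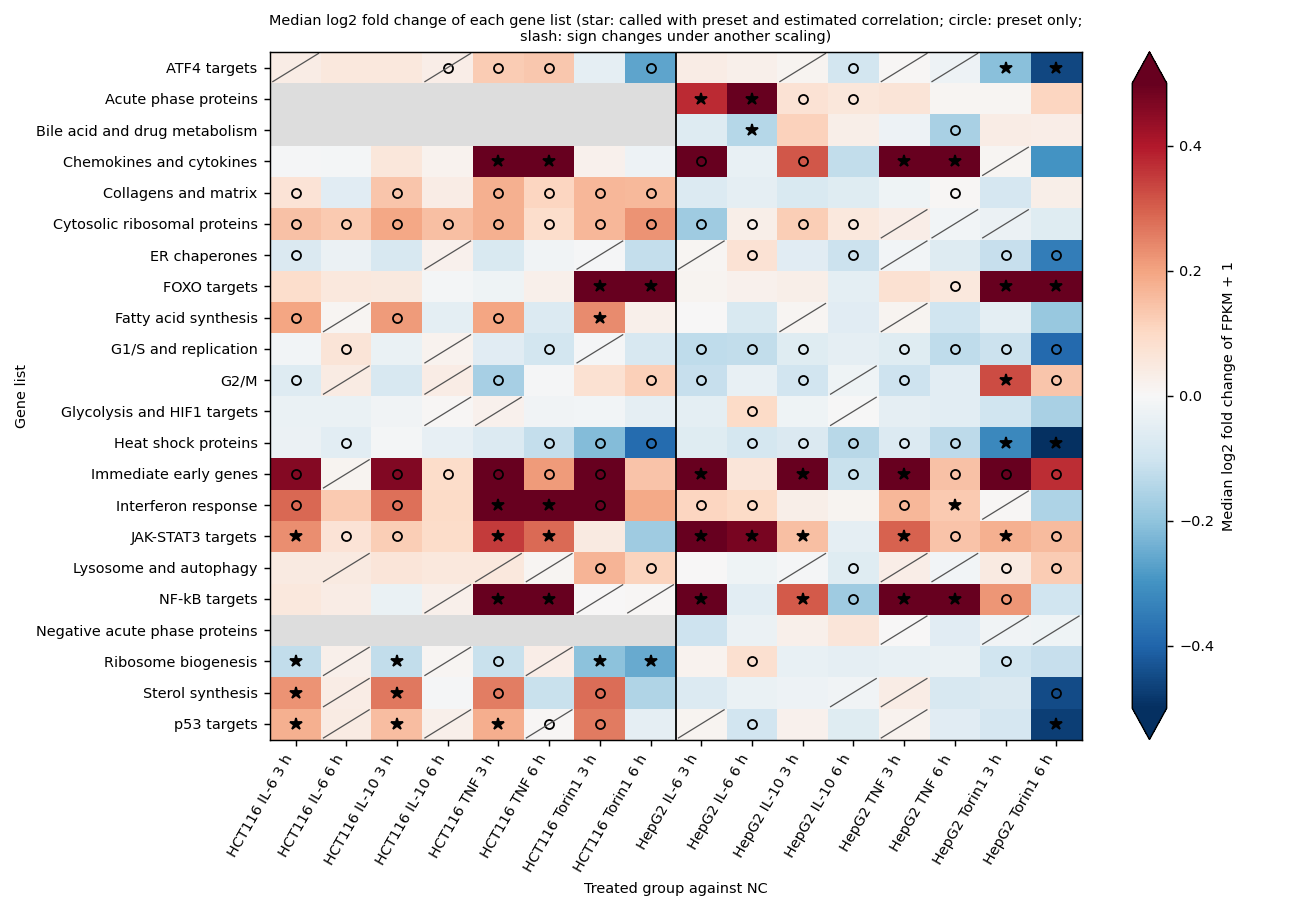
Median log2 change of each gene list (1 line of the heat map each) in each treated group against NC (columns), with colour for the median, grey where fewer than 5 members were tested, a star for lists called with the preset and the estimated correlation, a circle for the preset alone and a slash where another scaling turns the sign of the median. FOXO targets under Torin1 and NF-kB targets under TNF-α have stars in both lines, and acute phase proteins have stars under IL-6 in HepG2.

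The 3 h and 6 h libraries of each treatment were compared directly, without NC. In HCT116, AREG fell between 3 h and 6 h, from 410.1 ± 11.5 to 204 ± 13.2 FPKM (log2 -1.01, limma adjusted p = 4.19e-07) under IL-6 and from 468 ± 24.9 to 244 ± 44.4 FPKM (log2 -0.95) under IL-10. It fell from 509 ± 25.8 to 298 ± 16.7 FPKM (log2 -0.77) under TNF-α and from 605 ± 57.7 to 260.0 ± 35.3 FPKM (log2 -1.22) under Torin1. The chemokine genes CXCL8 (50.8 ± 2.59 to 6.28 ± 0.702 FPKM, log2 -2.83) and CCL20 (10.3 ± 1.5 to 2.16 ± 0.268 FPKM, log2 -1.83) fell under TNF-α. TIMP3 fell from 1.68 ± 0.157 to 0.91 ± 0.148 FPKM (log2 -0.49) and TIMP2 from 8.57 ± 0.231 to 6.9 ± 0.124 FPKM (log2 -0.28) under TNF-α.

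Immediate early genes went down under each treatment. Under IL-6 1 of 33 rose, 23 fell and 9 did not pass (1 rose and 25 fell adjusted over the list alone, camera adjusted p = 4.00e-23). Under IL-10 3 of 33 rose, 21 fell and 9 did not pass (3 rose and 22 fell adjusted over the list alone, camera adjusted p = 9.19e-16, adjusted p = 0.0779 with an estimated correlation). Under TNF-α 3 of 33 rose, 24 fell and 6 did not pass (3 rose and 25 fell adjusted over the list alone, camera adjusted p = 2.54e-13, adjusted p = 0.105 with an estimated correlation). Under Torin1 2 of 33 rose, 26 fell and 5 did not pass (2 rose and 26 fell adjusted over the list alone, camera adjusted p = 1.89e-15, adjusted p = 0.0810 with an estimated correlation). CCN1 was among the leading members in all 4, from log2 -1.86 under Torin1 to -1.43 under IL-6. Of the sterol synthesis genes, 17 of 25 fell and 8 did not pass (20 fell adjusted over the list alone, camera adjusted p = 1.04e-16) under IL-6. The count was 20 of 25 that fell and 5 that did not pass (21 fell adjusted over the list alone, camera adjusted p = 6.66e-18) under Torin1. Of the ribosome biogenesis genes, 28 of 40 rose and 12 did not pass (33 rose adjusted over the list alone, camera adjusted p = 4.61e-13) under IL-6. Under TNF-α, 1 of 10 rose, 8 fell and 1 did not pass (1 rose and 8 fell adjusted over the list alone, camera adjusted p = 3.31e-09) of the chemokines and cytokines. In the same step 5 of 25 rose, 15 fell and 5 did not pass (6 rose and 15 fell adjusted over the list alone, camera adjusted p = 3.66e-05, adjusted p = 0.0676 with an estimated correlation) of the NF-kB targets, ICAM1 at log2 -1.5. The step changed 2095 genes (1303 higher and 792 lower at 6 h) under IL-6, 2276 genes (1284 higher and 992 lower at 6 h) under IL-10, 4249 genes (2307 higher and 1942 lower at 6 h) under TNF-α and 3461 genes (1601 higher and 1860 lower at 6 h) under Torin1. For Torin1 the higher and lower counts were 1819 and 1682 with median-of-ratios factors, 2020 and 1438 with total reads.

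In HepG2, ANKRD1 fell between 3 h and 6 h under IL-6 from 118 ± 16.7 to 17.9 ± 2.84 FPKM (log2 -2.66, limma adjusted p = 2.22e-11), under IL-10 from 126 ± 27 to 26.1 ± 2.96 FPKM (log2 -2.21) and under TNF-α from 136 ± 4.33 to 28.5 ± 2.53 FPKM (log2 -2.22). THBS1 fell under each treatment, from 228 ± 21.3 to 54.7 ± 5.77 FPKM (log2 -2.04) under IL-6, with log2 -1.95 under IL-10, -1.57 under TNF-α and -1.19 under Torin1. TIMP1 rose from 22.1 ± 3.19 to 27.6 ± 0.299 FPKM (log2 0.32) under IL-6, a call lost without IL-6 3 h replicate 3 (log2 0.21, limma adjusted p = 0.0671). TIMP3 fell from 45.5 ± 2.37 to 31.3 ± 1.85 FPKM (log2 -0.52) under IL-6, from 53.9 ± 1.35 to 34.4 ± 0.43 FPKM (log2 -0.63) under IL-10 and from 65.1 ± 1.01 to 42 ± 2.95 FPKM (log2 -0.62) under TNF-α. SOCS3 rose further under IL-6 (log2 1.08), as did SERPINA3 (log2 0.71).

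Of the immediate early genes, 22 of 25 fell and 3 did not pass (22 fell adjusted over the list alone, camera adjusted p = 2.87e-23) under IL-6. Of 25, 24 fell and 1 did not pass (24 fell adjusted over the list alone, camera adjusted p = 2.82e-29) under IL-10. Of the NF-kB targets, 18 of 23 fell and 5 did not pass (19 fell adjusted over the list alone, camera adjusted p = 1.90e-14) under IL-6. Of 23, 19 fell and 4 did not pass (21 fell adjusted over the list alone, camera adjusted p = 1.83e-23) under IL-10, with NFKBIA from 149.9 ± 22.4 to 61.1 ± 3.08 FPKM (log2 -1.27). Under Torin1, 23 of 27 fell and 4 did not pass (24 fell adjusted over the list alone, camera adjusted p = 1.71e-16) of the p53 targets, CDKN1A at log2 -0.69. Of the sterol synthesis genes under Torin1, 21 of 24 fell and 3 did not pass (21 fell adjusted over the list alone, camera adjusted p = 2.29e-13). HMGCS1 stood at log2 -1.09. The step changed 2649 genes (1272 higher and 1377 lower at 6 h) under IL-6, 1805 genes (725 higher and 1080 lower at 6 h) under IL-10, 2867 genes (1355 higher and 1512 lower at 6 h) under TNF-α and 4102 genes (1920 higher and 2182 lower at 6 h) under Torin1. For IL-6 the higher and lower counts were 1354 and 1334 with total reads, 1327 and 1320 without IL-6 3 h replicate 1, 1255 and 1215 without IL-6 3 h replicate 2. They were 1359 and 718 with total reads for IL-10. For TNF-α they were 1515 and 1381 with median-of-ratios factors, 1939 and 1039 with total reads, and for Torin1 1772 and 1689 without Torin1 6 h replicate 1.

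Line differences were tested as the mean effect at 3 h and 6 h against NC in HCT116 minus that in HepG2. For IL-6, SOCS3 gave a log2 difference of -2.4 ± 0.095 (SE, limma adjusted p = 4.09e-22), TGM2 -2.36 ± 0.071, LRG1 -1.97 ± 0.064 and TIMP1 -0.75 ± 0.082, each lower in HCT116. For TNF-α, PLAUR (2.87 ± 0.133), BIRC3 (2.68 ± 0.103) and TGFA (1.12 ± 0.065) stood higher in HCT116, and FSTL3 (-2.3 ± 0.099), CXCL3 (-1.69 ± 0.114) and ID2 (-1.44 ± 0.048) lower. For Torin1, DDIT4 (2.24 ± 0.098) stood higher, and CCN2 (-1.72 ± 0.119) lower. For IL-10, AREG (0.77 ± 0.118, limma adjusted p = 1.94e-05, or 0.0677 with voom) stood higher in HCT116. AREG also did under IL-6 (0.39), TNF-α (0.72) and Torin1 (0.84).

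Under IL-6, 2 of 22 were higher, 18 lower and 2 did not pass (2 higher and 18 lower adjusted over the list alone, camera adjusted p = 5.31e-17) in HCT116 among the JAK-STAT3 targets. Under TNF-α, 16 of 23 were higher, 1 lower and 6 did not pass (17 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.12e-22) among the NF-kB targets. In the interferon response list 7 of 7 were higher (7 higher adjusted over the list alone, camera adjusted p = 1.31e-12), IFIH1 at log2 1.53. Of the p53 targets 12 of 26 were higher, 1 lower and 13 did not pass (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.44e-07). BBC3 stood at log2 1.41. Under Torin1, 21 of 26 were higher, 2 lower and 3 did not pass (21 higher and 2 lower adjusted over the list alone, camera adjusted p = 6.67e-09) among the p53 targets, PLK2 at log2 1.17. In the same test 20 of 24 were higher, 2 lower and 2 did not pass (20 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.26e-07, adjusted p = 0.0779 with an estimated correlation) among the sterol synthesis genes. The difference was called for 2742 genes (1673 higher and 1069 lower in HCT116) under IL-6, 2117 genes (1687 higher and 430 lower in HCT116) under IL-10, 1728 genes (933 higher and 795 lower in HCT116) under TNF-α and 4895 genes (2582 higher and 2313 lower in HCT116) under Torin1. For IL-6 the higher and lower counts were 1208 and 1419 with total reads, and for Torin1 2434 and 2438 with total reads. For TNF-α they were 870 and 887 with median-of-ratios factors, 664 and 1209 with total reads. For IL-10 they were 1240 and 588 with median-of-ratios factors, 870 and 808 with total reads.

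The genes that rose at least 2-fold in both lines were counted over 9273 genes tested in both and without a copy row, where the lines share no library. TNF-α at 3 h had 107 in HCT116 and 55 in HepG2, 36 of them shared against 0.635 for independent lists (one-sided Fisher's exact test, adjusted p = 2.02e-58). At 6 h 14 were shared of 62 and 22 (0.147 for independent lists, Fisher's exact test adjusted p = 4.84e-26), among them BIRC3, CCL20, CXCL8, ICAM1 and TNFAIP3. Torin1 shared 18 of 61 and 55 at 3 h (0.362 for independent lists, Fisher's exact test adjusted p = 9.30e-27) and 16 of 44 and 60 at 6 h (0.285, Fisher's exact test adjusted p = 7.80e-25), CCNG2, PIM1, UBALD2 and GABARAPL1 among the latter. IL-6 at 3 h shared 4 of 17 and 35 (CCN1, THBS1 and, named after their values were seen, MAFF and NAB2; 0.0642 for independent lists, Fisher's exact test adjusted p = 6.26e-07), and IL-10 2 of 19 and 14 (CCN1 and THBS1; 0.0287, Fisher's exact test adjusted p = 5.19e-04). Torin1 at 3 h also shared CCN1, MAFF and THBS1. Against IL-10, IL-6 at 3 h changed 0 genes 2-fold in HCT116. DNAJA1 and DNAJB1 were among the 3 that fell at least 2-fold in both at 6 h.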

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

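The tests of the shared 3 h change, of the genes with copy rows and of the hepatocyte transcripts in HCT116 were all chosen after the result was seen; the counts of other splits were planned.

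Effects at 6 h differed from those at 3 h, by limma, for 2095 genes under IL-6, 2276 under IL-10, 4249 under TNF-α and 3461 under Torin1 in HCT116. In HepG2 the counts were 2649, 1805, 2867 and 4102 in the same order. Effects differed between the lines for 2742, 2117, 1728 and 4895 genes. Among the genes the study is about, the log2 difference of the effect in HCT116 from that in HepG2 passed limma under IL-6 for TIMP1 -0.75, MMP15 -0.20, TGFA 0.29 and AREG 0.39. Under IL-10 it passed for MMP15 -0.20, TGFA 0.20, AREG 0.77 and HBEGF 0.51, AREG not passing with voom (limma adjusted p = 0.0677). Under TNF-α it passed for TIMP2 -0.35, TIMP3 -0.26, MMP14 0.22, MMP15 -0.18, TGFA 1.12, AREG 0.72 and HBEGF 0.73, and under Torin1 for TIMP3 -0.45, MMP14 0.50, TGFA -0.16, AREG 0.84 and HBEGF -0.52. Several of these calls were lost under an alternative. AREG was lost under IL-6 with a pseudocount of 0.1 (limma adjusted p = 0.103) and with voom (limma adjusted p = 0.506), and under TNF-α with voom (limma adjusted p = 0.195). TIMP3 under TNF-α was lost with the same pseudocount (limma adjusted p = 0.208) and with voom (limma adjusted p = 0.320). With no filter MMP15 was lost under IL-10 (limma adjusted p = 0.0576) and TNF-α (limma adjusted p = 0.0766), and TGFA under IL-10 (limma adjusted p = 0.0596) and Torin1 (limma adjusted p = 0.0664). TGFA under IL-10 was also lost with median-of-ratios factors (limma adjusted p = 0.0510) and total reads (limma adjusted p = 0.0880). Leaving out single libraries lost AREG and MMP15 under IL-6 (limma adjusted p up to 0.0686 and 0.0743), MMP15 and TGFA under IL-10 (up to 0.0881 and 0.0855), MMP14 and MMP15 under TNF-α (up to 0.111 and 0.159) and TGFA under Torin1 (up to 0.175).

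The counts were set against other splits of the same libraries. Every comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. The real split was in each the 1 with the most genes, and other splits called at most 4 genes, against real counts from 1317 to 11115. For the differences between lines 100 splits were used, the real one included. For IL-6 (real 2742, highest other 1803), IL-10 (2117 and 1969) and Torin1 (4895 and 3633) only the real split was that large. For TNF-α 3 were (1728 and 3221). The splits moved libraries between the 3 h, 6 h and NC groups of a line, so they cannot test a difference between lines. Why some called so many genes was not tested.

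The first pattern is that each treated group, IL-10 included, differed from NC in many genes (from 1317 to 6756), with IL10RA and IL10RB listed under the filter. Signalling by IL-10 as the whole cause stays open. The change from 3 h to 6 h under IL-10 uses no NC library. It followed that of TNF-α or Torin1 (Pearson's r at least 0.34, Spearman's rho at least 0.31). IL-10 signalling does not forbid this. A change that all treated libraries share at 3 h, from handling or medium, would need all pairs of treatments to follow each other, and the 6 Pearson correlations ran from 0.41 to 0.72 in HCT116 and from 0.3 to 0.61 in HepG2 (Spearman's rho 0.29 to 0.71 and 0.21 to 0.52; genes are not independent replicates). It stays open as a candidate explanation, since NC has no time label and no 3 h mock group was analysed here. A response to protein or medium that the design does not separate from the treatments stays open as well, untested.

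The second pattern is that 184 of 544 tested HCT116 genes with a copy row had a within-group SD of at least 0.5 log2 (33.8%), against 0.44% of the others (Fisher's exact test p = 6.09e-209), with 34.4% against 0.25% in HepG2. Counting error is argued against, since the share within 2 times the Poisson variance was 0.0%. Reads moving between the listed entries are argued against as well, since adding them up brought only 10.3% under the limit. Reads that match both copies and are counted in some libraries only may be the source, and no biological explanation was tested.

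The third pattern is a trace of abundant hepatocyte transcripts in HCT116, with ALB at 0.83 to 4.65 FPKM per library. Over the 15 markers without a copy row and above 50 FPKM in HepG2, a restriction made after a first result over all 16, the level was 0.0247% of that in HepG2 (median) and the correlation of log levels 0.989. Expression by HCT116 cells would let the ratios differ between genes, and they lay within 2.47-fold of each other. Reads carried over from HepG2 libraries may account for the trace, and whether in RNA, library or index is open; with HPX included the correlation was 0.766 and the ratios spread 155.1-fold.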

How the results depend on the processing

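Voom, total-read scaling and the fit without copy-row genes were added after seeing the data; the other alternatives were planned. Of the 29 comparisons, the count of called genes stayed within 1.5 times in 29 with a pseudocount of 0.1, in 29 with voom and in 29 without copy-row genes. With no filter 1138 genes were called for IL-6 at 6 h in HCT116 and 2717 for the TNF-α difference between lines, and with a filter of 5 FPKM 1090 for that difference and 7300 for NC between lines, where the stricter filter tests fewer genes. IL-10 at 6 h in HepG2 had 877 with median-of-ratios factors and 780 with total reads. Fits of only the 6 libraries compared, with fewer samples for the spread, called 1215 for IL-6 and 1051 for IL-10 at 6 h in HCT116, and 2221 for IL-6 and 1364 for IL-10 at 3 h in HepG2. Against IL-10, IL-6 in HCT116 called 27 at 3 h and 13 at 6 h, and TNF-α in HepG2 1817 at 3 h. For the other changes in count the cause was not tested.

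Leaving out each library in turn gave, for IL-6, IL-10, TNF-α and Torin1 in that order, 2865 to 3158, 3196 to 4221, 4016 to 4378 and 5590 to 5691 genes at 3 h in HCT116 and 1123 to 1464, 1295 to 2541, 3251 to 3512 and 5988 to 6256 at 6 h. In HepG2 it gave 3058 to 3651, 1407 to 1901, 2751 to 2962 and 4412 to 4613 at 3 h and 1646 to 1829, 552 to 1044, 2551 to 2800 and 6270 to 6402 at 6 h. For 6 h against 3 h it gave 1507 to 1773, 1714 to 2055, 3502 to 3879 and 2773 to 3126 in HCT116 and 1933 to 2647, 1246 to 1704, 2038 to 2651 and 3390 to 3850 in HepG2. The differences between lines ran 2067 to 2914, 1537 to 2350, 1418 to 1778 and 4484 to 4843, and NC between lines 10891 to 10942. The libraries that moved a count by over 1.5 times were, at 6 h in HCT116, IL-6 replicates 1 (1191) and 2 (1141) and NC replicate 3 (1123) for IL-6, and IL-10 replicate 1 (1295) for IL-10. For IL-10 in HepG2 they were IL-10 replicate 2 at 3 h (1407), and at 6 h IL-10 replicates 1 (813) and 3 (760) and NC replicates 1 (798) and 2 (552).

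Of the 165 list calls against NC, 47 held with an estimated correlation, and a replicate block gave 166. The numbers do not pair samples in the labels, and the mean correlation of the deviations of libraries with the same number was 0.008 in HCT116 (-0.144 to 0.187) and 0.023 in HepG2 (-0.17 to 0.335). As a hint from the data, 13 of 27 libraries in HCT116 and 19 of 27 in HepG2 correlated best with their own number, against 9.0 by chance. The block kept the count of called genes within 1.5 times in all 29 comparisons (ratio 1 to 1.07). Of the values of named genes under all alternatives, 4237 kept direction and side of the threshold, 69 lost the call, 9 gained one and 11 turned sign. All of the latter came with IL-10 in place of NC, at log2 AREG -0.19, CCN1 -0.22, CDKN1A -0.06, DUSP5 -0.09, GDF15 -0.25, HBEGF -0.21, OVOL1 -0.07, PIM1 -0.13 and STARD4 -0.15 for IL-6 at 3 h in HCT116; TIMP3 -0.24 for IL-6 at 3 h in HepG2; TIMP3 -0.14 for Torin1 at 3 h in HepG2, and the cause was not tested. At the lowest depth 3 reads on 1 kb are worth 0.0733 FPKM in HCT116 and 0.0708 in HepG2, and the highest library reached 0.213 FPKM of TIMP4 and 0.0467 of EGF in HCT116, near what this depth can show.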

Other observations

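Set against the IL-10 libraries of the same hour, IL-6 in HCT116 differed in few genes. STAT3 was 18.1 ± 1.21 FPKM against 12.6 ± 0.219 (log2 0.49, limma adjusted p = 1.46e-06) at 3 h and 15.1 ± 0.119 FPKM against 10.9 ± 0.136 (log2 0.43, limma adjusted p = 1.46e-05) at 6 h. DTX3L was 6.47 ± 0.648 FPKM against 4.59 ± 0.208 (log2 0.41) at 3 h and 5.92 ± 0.284 FPKM against 4.36 ± 0.135 (log2 0.37) at 6 h, OSMR, a receptor chain of the same cytokine family, 10.9 ± 0.533 FPKM against 8.7 ± 0.205 (log2 0.30) at 3 h and IFITM2 34.8 ± 2.52 FPKM against 28.4 ± 1.12 (log2 0.28) at 6 h. Of the mitochondrially encoded genes, a sign of RNA composition, 3 of 13 rose and 10 did not pass (camera adjusted p = 4.22e-15, adjusted p = 0.0598 with an estimated correlation) at 3 h and 2 of 13 rose and 11 did not pass (camera adjusted p = 3.40e-17) at 6 h, ND2 at log2 0.29 and 0.37. In all, 27 genes passed limma at 3 h and 13 at 6 h, 14 and 8 of them also called against NC with the same sign. Of the JAK-STAT3 targets, 5 of 22 rose and 17 did not pass (camera adjusted p = 1.10e-07) at 3 h and 1 of 22 rose and 21 did not pass (camera adjusted p = 0.0383, adjusted p = 0.339 with an estimated correlation) at 6 h. In HepG2 the acute phase proteins stood apart from IL-10 under IL-6: 15 of 21 rose and 6 did not pass (camera adjusted p = 3.23e-18) at 3 h and 17 of 21 rose and 4 did not pass (camera adjusted p = 3.43e-21) at 6 h. The short noncoding RNA BCYRN1 was higher in the HepG2 IL-10 libraries than in 5 of the 6 other treated groups of the same hour. At 3 h it was 13.7 ± 3.54 FPKM against 55.5 ± 21.2 (log2 -1.89) under IL-6, with log2 -1.82 under TNF-α and -2.13 under Torin1. At 6 h BCYRN1 was 10.2 ± 0.728 FPKM against 47.8 ± 10.0 (log2 -2.1) under TNF-α and at log2 -2.52 under Torin1, while under IL-6 it did not pass (log2 -0.70, limma adjusted p = 0.0668). The treatment protocol does not describe IL-10 handling, so whether those libraries shared a run with the others is open. TNF-α lowered genes in HCT116 against IL-10 at 3 h, with ID2 at 72.2 ± 2.07 FPKM against 232 ± 6.15 (log2 -1.67) and DUSP6 at 15.1 ± 0.881 FPKM against 33.7 ± 0.845 (log2 -1.11). The IL-10 comparison was planned, and the genes printed here were chosen from it after their values were seen.

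Some lists gave little. Over the 16 treated groups, glycolysis and HIF1 targets were called higher against NC by camera in 1 of 16, replication-dependent histones in 2 of 16 and the receptors and targets of the treatments in 2 of 16, and none of these calls held with an estimated correlation. The TIMP, MMP, colon epithelium, blood cell and fibroblast lists had too few tested members for camera against NC.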
